A study of Mus musculus with 1000 samples.

How the data were processed

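Whole brain without cerebellum was collected from mice of generation 3, usually 8 to 12 weeks old, whose founders had received 3 doses of ENU at 100 mg per kg, per the labels' protocols. The libraries of both Inpp5d stems carry another mark in their names (G2RN), whose meaning the labels do not state. RNA was converted to 3' cDNA libraries with the SMART-Seq v4 3' DE chemistry, which counts transcripts at their 3' ends. The input was 4 ng of total RNA and amplification took 8 cycles, per the labels' protocols. Libraries were handled in batches of 1152 on 12 plates of 96 wells. Each row of 12 was pooled, and 400 pg of each of the 96 pools went into tagmentation. Reads were processed with GSNAP against GRCm38, per the submitters' processing notes, and the GSNAP version is not given in the sources used here.

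The single table analysed here was a lookup deposited by the authors. It had a row number, a library name and a part label for each of 23231 libraries, and no measurement. The 3 parts held 7743, 7743 and 7745 names. All 1000 library names of this series were found by exact match, all of them in the first part, and the other 22231 rows belonged to libraries not described in the labels used here. Their names were used only for counts of names. Expression values lie in the parts that the table points to and were not used here. The gene tests fixed before the data were examined (Inpp5d W8X genotypes, Paralysis phenotype, and values for the S308X, Map4k5 and Plod2 libraries) and the marker lists that went with them, for microglia, interferon response, astrocytes, oligodendrocytes, neurons, vessels, choroid plexus and blood, were therefore not run. The rule for named genes reduced to the gene symbols in the candidate labels. Depth is unknown, so no precision of an expression value can be given.

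The labelled subset held 66 of the 1000 libraries and 934 lay outside it. Groups were taken from the candidate, genotype and phenotype labels. Libraries were split by name into a stem (ENU and the number after it), an animal number, a plate, a well and a pool index. The stem was taken as marking related animals, because the protocol describes about 12 siblings per pedigree and the stems have a median of 12 libraries. The labels do not define it. A plate row also holds 12 libraries, and stems reach 75 libraries over the whole lookup table, so the match does not establish kinship. The well was read as a plate position. For each of the 22 plates the pool index rose with the row letter, counting row A as the number after a multiple of 8. Plate and row were therefore taken to define a cDNA pool. Up to 3 plates shared the same run of pool indices, so the libraries came from at least 3 batches of 1152. The batch of each plate was not given.

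The clustering of stems in pools was tested by shuffling stems within plates, and the spread of the subset over plates by shuffling the subset label over whole stems, each with 100000 draws (10000 in the alternatives and 1000 for the whole lookup table). The number of stems holding the animals with a second library was tested by random draws of the same number of animals. Fisher's exact test was used for the phenotype and the pool. The shares of animals with a second library, in the subset and outside it, are given with exact Clopper-Pearson 95% intervals. These intervals cover counting error only, and other shares are given without an interval. The shuffling test was tested on simulated data: 6 of 200 random layouts gave p under 0.05, and 0 of 500 draws reached an ordered layout. The simulated plates were full and some simulated stems were smaller than any in this series. The check therefore covers the method and not the exact layout of these plates. Alternatives were a looser name match, other definitions of pool and stem, the whole lookup table, and leaving out each Paralysis library.

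The position of 1 further labelled residue is not reported here. Candidate residues were located in GENCODE M21, an annotation of GRCm38, the build named in the processing notes. Every protein-coding transcript with an annotated start was translated, and the labelled residue number was looked up in each. Coordinates are 1-based. This step was added after the table was found to hold names only. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Biopython 1.88 and matplotlib 3.10.9.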

Results

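The series held 1000 RNA-seq libraries, each made from the whole brain of a single mouse after removal of the cerebellum. The mice descended from C57BL/6NCrl males treated with N-ethyl-N-nitrosourea (ENU), a chemical that introduces point mutations into the germ line. The screen was built to find animals with abnormal inflammation in the brain by their transcripts and to trace those states to candidate variants by exome sequencing. The table analysed here listed library names and the part of the processed data that holds each library. It held no counts or expression values, so the expression of genes, including that of the candidate genes, was not analysed here, and the depth of the libraries is unknown. The measurements below are the composition of the groups, the genomic position of 3 of the labelled candidate residues, and the placement of the groups on plates and in cDNA pools.

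Of the 1000 libraries, 66 belonged to a labelled subset and the rest of the screen lay outside it. The subset comprised 6 name stems, each a number shared by several library names and taken here to mark related animals. Inpp5d, which encodes an inositol phosphatase of blood cells and microglia, was the candidate in 2 of them, with 15 libraries labelled S308X and 10 labelled W8X. Map4k5, which encodes a protein kinase of the MAP kinase pathways, was the candidate in 1 stem (W649L, 12 libraries). Plod2, which encodes a lysyl hydroxylase that modifies collagen, was the candidate in another (L262Q, 12 libraries). A further stem with 5 libraries was labelled Paralysis and the last, with 12 libraries, was labelled Unaffected.

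Few of the subset libraries carried a genotype. Homozygous, heterozygous and wild-type animals (m/m, m/+ and +/+ in the labels) were given for 11 of the 66 libraries. Among the W8X libraries there were 2 m/m, 2 m/+ and 2 +/+ animals, and 4 had no genotype. The S308X libraries held 1 m/m, 1 m/+ and 1 +/+ animal beside 12 without a genotype. Map4k5 W649L and Plod2 L262Q had 1 m/m library each, both labelled with a low MG signature, beside 11 libraries of unstated genotype in each stem. A primary phenotype was given for 7 libraries, namely those 2 m/m animals and the 2 affected and 3 unaffected animals of the Paralysis stem. A histology block was given for 17 libraries. The W8X +/+ animals were both in block 6, the m/+ animals were both in block 4, and the m/m animals were divided between the blocks, 1 in each.

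Labelled residues were located on the annotated coding transcripts to give the genomic position of 3 of the candidates (GRCm38, GENCODE M21). The Inpp5d residue S308 lay in a coding exon of the principal transcript Inpp5d-210, on the forward strand of chromosome 1. The gene (ENSMUSG00000026288.14) spans positions 87620312 to 87720507. This serine was encoded by TCA at positions 87683749 to 87683751 in exon 9 of 27, 25.9% into the protein of 1191 residues, within the transcript sequence GAGGTGAAGTCAGAGTCCCTG. S308 was found in 2 of the 6 coding transcripts examined. In Inpp5d-201 the same serine codon was S307. In Inpp5d-208 and Inpp5d-211 it was residue 45.

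The Plod2 and Map4k5 labels differed in how they matched the annotation. Plod2 leucine L262 was present in both coding transcripts (2 of 2). It was encoded by CTG at positions 92591306 to 92591308 of chromosome 9, in exon 8 of 19 of the principal transcript (ENSMUST00000070522.13), 35.5% into the protein, within AAGATTCTCCTGAATTACTTT. The gene (ENSMUSG00000032374.14) spans 92542223 to 92608428 on the forward strand. Tryptophan W649 of Map4k5 was found in only 1 of 4 coding transcripts, ENSMUST00000171211.7, which is not the principal one. There it was encoded by TGG at positions 69815774 to 69815776 of chromosome 12, in exon 25 of 30, within GCATCTTCCTGGTTTACAGAA as read on the reverse strand. The same codon was W716 in the principal transcript (ENSMUST00000049239.7) and in ENSMUST00000110570.7, and W697 in ENSMUST00000110567.7. At the labelled number the principal transcript had a leucine, L649. The transcript by which the label was numbered is not given in the sources used here. The Map4k5 position therefore rests on the match to ENSMUST00000171211.7. The gene (ENSMUSG00000034761.15) spans 69803750 to 69893200.

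The labels gave amino acid changes, and the base changes themselves were not given in the sources used here. Counting from the first base of the start codon, a single base change can turn S308 of Inpp5d into a stop as C923A or C923G. Only 1 single base change gives each missense label, which is T785A for Plod2 L262Q and G1946T for Map4k5 W649L in ENSMUST00000171211.7.

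**Figure D1:**
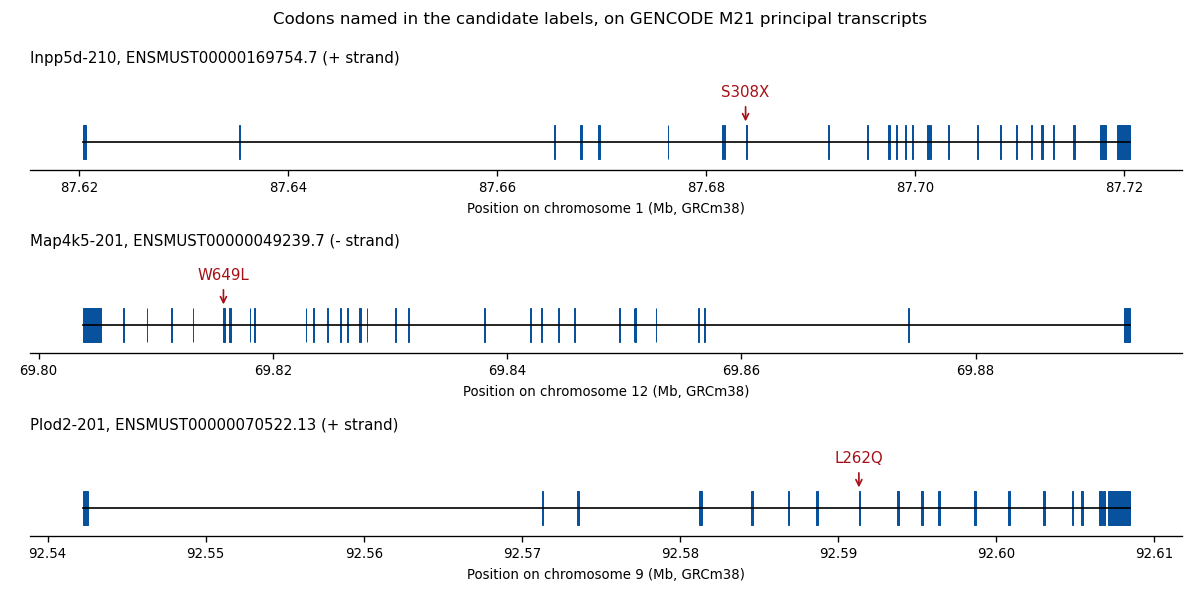
Exons (blue boxes, to scale) and introns (line) of the principal transcripts of Inpp5d, Map4k5 and Plod2 along the chromosome in Mb (GRCm38), with arrows at the codons of 3 labelled residues. All 3 codons lie in coding exons, and the Map4k5 codon labelled W649L is W716 in the transcript drawn.

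The grouping of the series by name stem was read from the library names. The 1000 libraries fell into 92 name stems with a median of 12 libraries and a range of 4 to 15. There were 12 libraries in 73 stems and 6 in 15 stems, and 4 stems had another number. The libraries lay on 22 plates in 86 plate rows, with 12 to 96 libraries of this series per plate. In the protocol the 12 libraries of a plate row were pooled after cDNA amplification and carried through tagmentation as 1 pool, so libraries of a row shared every later step.

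Within this series, libraries of the same stem almost always shared a cDNA pool. The libraries of 90 of the 92 stems (97.8%) lay wholly in 1 pool, and the other 2 stems lay in 2 pools each. Over the whole lookup table, which lists further libraries of some of these stems, the share was lower, at 1667 of 1991 stems (83.7%). When stems were shuffled among the libraries of each plate, a mean of 5.08 stems and at most 8 lay in 1 pool (one-sided permutation p = 1e-05, the smallest that 100000 draws can give). Plates neuro2118, neuro2130, neuro2133 and neuro2134 held libraries of this series in only 1 row. Their stems stayed in 1 pool in every shuffle and make up nearly all of that mean. Both stems divided between pools belonged to the subset, namely Inpp5d S308X and Paralysis. The S308X stem has 15 libraries in this series, more than the 12 of a plate row, so it could not lie in 1 pool. The Paralysis stem, with 5 libraries, was small enough to, but the W8X stem took columns 1 to 10 of row F on plate neuro2127. The Paralysis libraries took columns 11 and 12 and ran on into row G, where the S308X libraries followed from column 4.

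Affected and unaffected animals of the Paralysis stem did not share a pool. Both affected libraries were in row F of plate neuro2127, in columns 11 and 12, and all 3 unaffected libraries were in row G, in columns 1 to 3. Phenotype and pool were therefore fully confounded in these 5 libraries. Fisher's exact test (two-sided) gave p = 0.1, the smallest that 2 libraries against 3 allow.

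The genotyped Inpp5d animals were placed more evenly over pools, but those of the W8X stem not over histology blocks. There +/+ (both block 6) and m/+ (both block 4) were fully separated by block. All 6 genotyped W8X libraries lay in a single pool, row F of the same plate, with +/+ in columns 2 and 10, m/+ in columns 4 and 6, and m/m in columns 3 and 5. The m/m, m/+ and +/+ S308X libraries were all in row H, in columns 2, 5 and 6, whereas 9 of the 12 S308X libraries of unstated genotype were in row G. With 2 libraries per genotype, an exact permutation test of m/m against +/+ in the W8X stem has a smallest two-sided p of 0.333. This limit belongs to the permutation of labels, and the planned gene test of these genotypes, a different test, was not run. With 1 library per genotype the S308X comparison has no replicate check. The Map4k5 m/m library shared row G of plate neuro2061 with the 11 other libraries of its stem, and the Plod2 m/m library shared row A of plate neuro2062 with the 11 others of its stem.

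**Figure D2:**
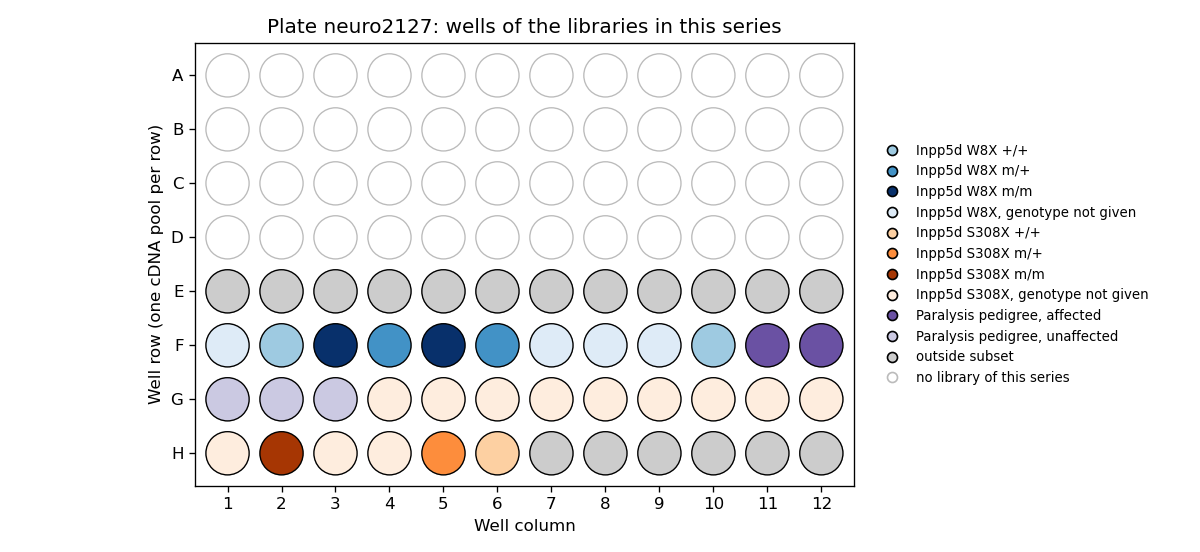
Wells of plate neuro2127 by column (horizontal axis) and row (vertical axis, each row a cDNA pool), with each library of this series coloured by its group and open circles for wells without a library of this series. The 6 genotyped Inpp5d W8X libraries share row F, and the 2 affected Paralysis libraries in row F are separated from the 3 unaffected libraries in row G.

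Some subset stems shared a plate and others did not. The 3 stems labelled Inpp5d S308X, Inpp5d W8X and Paralysis shared plate neuro2127, which held 30 subset libraries, while Map4k5 W649L, Plod2 L262Q and the Unaffected stem (plate neuro2128, row D) were each on a plate of their own within the subset. The 6 subset stems thus occupied 4 plates, against a median of 5 for 6 stems drawn at random (one-sided permutation p = 0.131, 100000 draws), which is within chance. Among the libraries of this series, no plate held both the Unaffected stem and a candidate stem, so a comparison between them would also be a comparison between plates.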

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

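The alternatives described here were chosen before the data were examined. None changed a call, but some calls could hardly change. The Paralysis call could not, whichever library was left out. Name matches were called unchanged within a wide band, and medians within the standard deviation of libraries per stem (2.45). All 1000 library names were also found when case and the text from the pool index on were ignored, and matching on the animal alone found 1034 rows, because 34 animals have a second library. The share of stems in a single cDNA pool was 97.8% in the series, 98.6% among stems with 12 or more libraries and 83.7% over the whole lookup table, and each lay above every shuffled layout (permutation p = 1e-05, 1e-04 and 0.001, the smallest that the draws can give). On plates in place of pools the share was 100.0% (p = 1e-04 with stems shuffled over all plates). The median number of libraries per stem was 12 in the series, over the lookup table and with the longer stem. The subset stems occupied 4 plates (p = 0.131) and 6 pools (p = 0.883). Leaving out each Paralysis library in turn gave Fisher's exact p of 0.25 to 0.333, and no design of this size can reach 0.05. The alternatives planned for the gene tests (DESeq2 size factors, no low-count filter, each replicate left out) were not run, as no counts were analysed. No paired analysis was possible because the groups have no replicate numbers in the labels and no measured values were compared.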

Other observations

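The tests in this part were chosen only after the names had been seen. The lookup table covers more animals of the 2 Inpp5d stems and the Paralysis stem than this series does. The stem of Inpp5d S308X had 39 library names in the table, of which 15 belong to this series, and that of Inpp5d W8X had 52 names from 45 animals, of which 10 belong here. The Paralysis stem had 18 names from 17 animals, of which 5 belong here. By contrast the stems of Map4k5 W649L and Plod2 L262Q had 1 further name each but no further animals, with 12 animals each in the table and 12 libraries each here, and the Unaffected stem had no further names. Gene symbols stood in the names of 2 stem families, Inpp5d (39 names) and Ms4a7 (19 names). The genotypes of the further animals were not analysed here.

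The separation of affected and unaffected Paralysis animals into different pools has a possible technical explanation, namely wells filled stem after stem in order of animal number. On plate neuro2127 the W8X stem ended at column 10 of row F, so only columns 11 and 12 of that row were left. Order of animal number alone would not divide a stem of 5 libraries between rows. The 5 Paralysis wells followed animal number, as did the wells of the other stem that lay in 2 pools. The median over the 92 stems of the rank correlation between animal number and well order was 1.0 (permutation p = 1e-04, the smallest that 10000 draws can give, with a highest shuffled median of 0.17). Strictly ascending order held in 52 stems, against 0.071 expected by chance. The order was broken in 40 stems, with rank correlations down to -0.322. These include the Map4k5 W649L stem (0.853) and the Plod2 L262Q stem (0.685), so the order was common but not a fixed rule. A placement chosen by phenotype was not tested and stays open, because in these 5 animals phenotype follows animal number too. Either way, an expression difference between these 5 libraries could not be told from a pool difference without further libraries.

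A second library was listed for 34 of the 1000 animals, and all 34 were on plates whose names end in rep, a mark the labels do not explain. They came from only 21 stems, with up to 4 animals per stem. Random draws of 34 animals gave a median of 29 stems (one-sided permutation p = 7e-05), which argues against animals drawn singly at random. Since 90 of the 92 stems lay wholly in a single pool, the test cannot tell a choice by stem from one by pool or plate. The subset held 2 of the animals with a second library, or 3.03% of its animals (exact 95% interval 0.369 to 10.5%), against 32 outside it, or 3.43% (2.36 to 4.8%). These intervals treat animals as independent. The animals with a second library gathered in few stems, so the intervals may be too narrow. The difference of -0.40 percentage points (one-sided permutation p over stems = 0.477) leaves open whether the subset was favoured, since 2 animals are too few to decide. Those 2 were the Plod2 L262Q m/m animal labelled with a low MG signature and a Map4k5 W649L animal of unstated genotype. Of the second libraries, 17 were in the same part of the processed data as the first and 17 in another, so those 17 repeat pairs can be compared only across parts.

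Over the whole table, 3.16% of 22517 animals had 2 or more libraries, and for 58.9% of those the libraries lay in 2 parts. Most plates were kept together, with 94.2% in a single part and 14 divided between 2.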
